A study of Mus musculus with 4 samples.

How the data were processed

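RNA was measured in 4 mouse testis libraries collected at postnatal day 14, 2 labelled Znhit1_KO and 2 labelled CTRL. Per the labels' protocols, total RNA came from fresh testes, poly(A) RNA was purified with beads, and over 40000000 reads per sample were sequenced on an Illumina NovaSeq for 2 independent biological replicates. The series' design text speaks of germ cells, whereas the sample labels give the source as testis and the cell type as testis cells; no purification of germ cells is described in the sources used here. The strandedness of the libraries is not given in the sources used here, so reads of overlapping or antisense genes could not be told apart.

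Per the submitters' processing notes, the authors used the mm10 build, cutadapt 2.5, HISAT2 2.2.1, StringTie 2.2.1 and DESeq2 1.38.3. The order and settings of these steps, the counting method and the annotation are not given in the sources used here. The deposited gene table holds whole-number values for 55335 genes that sum to between 129531714 and 157790457 per library, above the number of reads stated. Among low values, 4, 8, 12 and 16 occurred more often than their neighbours; in CTRL replicate 1, 1109 genes had the value 4 against a mean of 736 for the adjacent values. The values were therefore taken as estimated counts made by the authors from read coverage, and not as numbers of reads, so that counting precision computed from them is overstated. The authors' deposited comparison table holds TPM per library, mean normalised signal (a base mean over libraries), log2 fold changes, their standard errors and Wald statistics (scores), and p-values with adjusted p-values for 25236 genes. It marks genes as up or down; every marked gene had an adjusted p of at most 0.0497 and an absolute log2 change of at least 1.005. TPM values were normalised by the authors to transcript length and library total and were used only as described values.

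Each column was matched to a library by its name, and no column of other samples was used. Symbols were taken from the deposited table. Of the 55335 gene identifiers, 55154 were found without their version in GENCODE M21 (mm10), which gave chromosome, position, transcript length and GC content. Replicates were compared before averaging: 2.89% of detected genes had equal counts in the CTRL pair and 3.00% in the Znhit1_KO pair, and no library was counted as a duplicate.

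The deposited counts were already whole numbers and were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter by group, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The filter left 24116 genes. CPM values were normalised with the TMM factors, and log2 CPM used a prior count of 2. Standard errors of log2 changes were taken from the F statistic. The common biological coefficient of variation was 0.349. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives. Counts were simulated with the means, library sizes and fitted dispersion trend of these 4 libraries, for 24116 genes that varied independently. On them edgeR called 14, 24, 33 and 41 of 50 genes changed by 2-, 4-, 8- and 16-fold, with 1 false call. DESeq2 called 20, 37, 35 and 41, with 30 false calls. No difference shared by many genes within a group was simulated, so these rates need not hold for the real libraries.

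There were 27 gene lists, fixed before the data were examined, covering germ cell stages, meiotic functions, H2A.Z deposition and removal, and markers of the other cell types a testis holds. Each was tested two-sidedly with camera on log2 CPM at a preset inter-gene correlation of 0.01, with adjustment over the 27 lists, and again with a correlation estimated from the libraries and with fry. On simulated data a shifted list passed and 5 of 200 unshifted lists had an unadjusted p under 0.05. The simulated genes varied independently, whereas the estimated correlation was 0.566 for the flagellum list. The simulation therefore does not show that preset camera p-values hold for lists whose members vary together. Members were also adjusted over the list alone. X-linked genes were tested against all others with camera, and shares of calls were compared with Fisher's exact test, two-sided.

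The genes named were fixed before the data were examined: Znhit1; of each list up to 4 members past the threshold with the lowest p, and where fewer than 2 passed, the members of highest mean count to make 2; and the 10 highest and 10 lowest log2 changes among called genes with a symbol other than a clone name, a mean of at least 5 CPM and no overlap between groups. All members of the H2A.Z, pachytene and piRNA lists could be named. Since the edgeR test called 0 genes, the parts of the rule that need calls were applied to the authors' deposited calls, a choice made after the data were seen. Members that passed when adjusted over the list alone, sex-linked calls and some genes in the closing section were named after their values were seen.

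Alternatives chosen beforehand were DESeq2, limma-voom, DESeq2 size factors, total count scaling, scaling on the Sertoli list (with 0.5 added to each count), no filter, a filter of at least 50 counts in 2 libraries, the replicate number as a block, a test against a fold of 2, and leaving out each library. With a library left out, the lone sample of its group was assumed to vary like the other group. Counts divided by 4, and DESeq2 combined with other choices, were added after the data were seen. For the closing section, lists were set against 10000 random lists matched in 10 bins of mean expression, 8 of transcript length and 5 of GC content, or in 50 bins of expression for transcription factors. The transcription factor families were defined by symbol prefix after the calls had been seen, and genes that only share a prefix were then removed and hyphenated symbols added. Values of some of their members are not reported here.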

Results

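Gene expression was measured by poly(A) RNA sequencing of whole mouse testes at postnatal day 14, in 2 libraries labelled Znhit1_KO and 2 labelled CTRL. ZNHIT1 is a subunit of the SRCAP chromatin remodelling complex, which places the histone variant H2A.Z in nucleosomes. At this age the most advanced germ cells of the juvenile testis are spermatocytes in meiotic prophase. The series concerns pachytene gene expression and meiotic progression, and the comparison asks which transcripts differ when Znhit1 is disrupted. The estimated counts summed to 129531714 and 136178177 in CTRL replicates 1 and 2, and to 157790457 and 136732861 in Znhit1_KO replicates 1 and 2. Mitochondrially encoded genes took 4.12% and 3.52% of counts in CTRL and 4.12% and 3.12% in Znhit1_KO. Across genes, log2 CPM correlated at r = 0.969 between the CTRL libraries and 0.974 between the Znhit1_KO libraries; the lowest value of any pair, 0.942, was between CTRL replicate 2 and Znhit1_KO replicate 1.

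The Znhit1 transcript was lower in both Znhit1_KO libraries than in either CTRL library. Znhit1 (ENSMUSG00000059518.14, protein-coding, chromosome 5, 136982164 to 136988021, mm10) stood at 24.6 ± 10.3 CPM in CTRL (SD, n = 2) and 2.64 ± 0.712 CPM in Znhit1_KO (SD, n = 2). The authors' TPM values were 55.4 and 90.2 in CTRL replicates 1 and 2 and 8.0 and 5.24 in Znhit1_KO replicates 1 and 2. The log2 change was -3.22 (SE 0.403), with an unadjusted edgeR p of 0.000361 and an adjusted p of 0.264 over all genes. The authors' deposited table gives a log2 change of -3.23 and an adjusted p of 1.14e-14. Of the 20 other members of the list on H2A.Z deposition and removal none passed when adjusted over the list alone with edgeR, and Srcap (-0.12, SE 0.216), H2afz (-0.14, SE 0.285) and Vps72 (0.030, SE 0.176) had log2 changes within their standard errors. Mbtd1 (-0.56, SE 0.244), Actr6 (-0.44, SE 0.247), Epc2 (-0.38, SE 0.156), Ing3 (-0.38, SE 0.182) and Ruvbl1 (-0.32, SE 0.163) had larger ones, and with Znhit1 made up the 6 members lower in both Znhit1_KO libraries than in both CTRL libraries. The list of 21 had a median log2 change of -0.14 and a camera adjusted p of 0.0707, with p = 0.395 with an estimated correlation. Its median was -0.0080 without CTRL replicate 2 and -0.44 without CTRL replicate 1, where it passed (adjusted p of 0.0221), and it also passed with Sertoli list scaling (adjusted p of 0.0445).

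Among the largest decreases marked in the authors' deposited table, Adam3, a sperm surface protein, stood at 15.8 ± 11.1 CPM in CTRL and 0.904 ± 0.473 in Znhit1_KO (SD, n = 2), Slc13a5, a citrate transporter, at 12.3 ± 9.14 and 0.466 ± 0.176, and Ccdc38 at 26.4 ± 16.9 and 1.66 ± 0.580. The log2 changes of Slco6c1 (-4.71, SE 0.780), Ppp3r2 (-4.58, SE 0.995), Ccdc175 (-4.52, SE 0.803), Erich2 (-4.06, SE 0.711) and Ccdc144b (-3.96, SE 0.465) were of similar size. Tcp10c (-4.05, SE 0.713) and Tcp10b (-3.96, SE 0.966) are near-identical copies, and the division of reads between them is uncertain. Among genes marked higher in the authors' deposited table were the steroidogenic enzyme gene Cyp11a1 (2.21, SE 0.523), Cyp4f17 (1.91, SE 0.301), the cell cycle inhibitor gene Cdkn1c (1.72, SE 0.247), Srgap1 (1.34, SE 0.307), the immediate early gene Fosb (1.28, SE 0.342), Ssh3 (1.20, SE 0.215), Helt (1.16, SE 0.275), Plxna4 (1.16, SE 0.270), Tgfb2 (1.11, SE 0.308) and Hoxd9 (1.08, SE 0.298). The authors' deposited table marks 882 genes, 812 lower and 70 higher, so that 92.1% of its calls are lower. All 807 of the lower and all 67 of the higher calls that were tested here had the same sign in the edgeR fit and no overlap between groups. Those calls were made from the same 4 libraries, and the log2 changes of the 2 fits correlated at 0.9994, so this is no independent check.

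The edgeR quasi-likelihood test called 0 of 24116 genes at an adjusted p of 0.05 and 0 with a fold of at least 2; the lowest adjusted p was 0.264. At an unadjusted p under 0.05 there were 2590 genes, 1868 lower and 722 higher, while parting the same libraries by replicate number, across the groups, gave 2386. DESeq2 called 1027 genes, 925 lower and 102 higher, limma-voom called 0, and the 882 genes of the authors' deposited table were all among the 924 that DESeq2 called here with a fold of at least 2. Both Znhit1_KO libraries lay below both CTRL libraries for 21.3% of genes and above both for 21.8%, where chance gives 16.7% in each direction. Genes vary together, so shares above 16.7% can arise without a difference between the groups. Without CTRL replicate 1, edgeR called 754 genes, and without any 1 of the other libraries 0. DESeq2 called 1357 genes without CTRL replicate 1, 283 without CTRL replicate 2, 474 without Znhit1_KO replicate 1 and 824 without Znhit1_KO replicate 2.

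Genes of the sperm flagellum and motile cilium were lower as a group. Cfap54, a central apparatus protein of the axoneme, stood at 44.3 ± 6.06 CPM in CTRL and 8.66 ± 0.960 in Znhit1_KO (SD, n = 2), and the axonemal dynein heavy chain gene Dnah2 at 68.6 ± 13.8 and 17.1 ± 1.16. The log2 changes of the dynein genes Dnah12 (-2.65, SE 0.296), Dnah6 (-3.33, SE 0.518) and Dnah8 (-1.85, SE 0.32) had the same sign. Of the 66 members, 63 had a negative log2 change, and 54 were lower in both Znhit1_KO libraries than in both CTRL libraries. Adjusted over the list alone, 51 were called lower by edgeR, against 0 adjusted over all genes, while the authors' deposited table marks 40 lower. The median log2 change was -1.63, with a camera adjusted p of 9.44e-23; p = 0.168 with an estimated correlation, and the estimated correlation itself was 0.566. Mean log2 CPM of the list relative to all 4 libraries was 0.35 and 1.21 in CTRL replicates 1 and 2 and -0.95 and -0.60 in Znhit1_KO replicates 1 and 2. In the same libraries the 26 Sertoli cell markers had a median log2 change of 0.41. Without CTRL replicate 2 the flagellum median was -1.08.

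**Figure D1:**
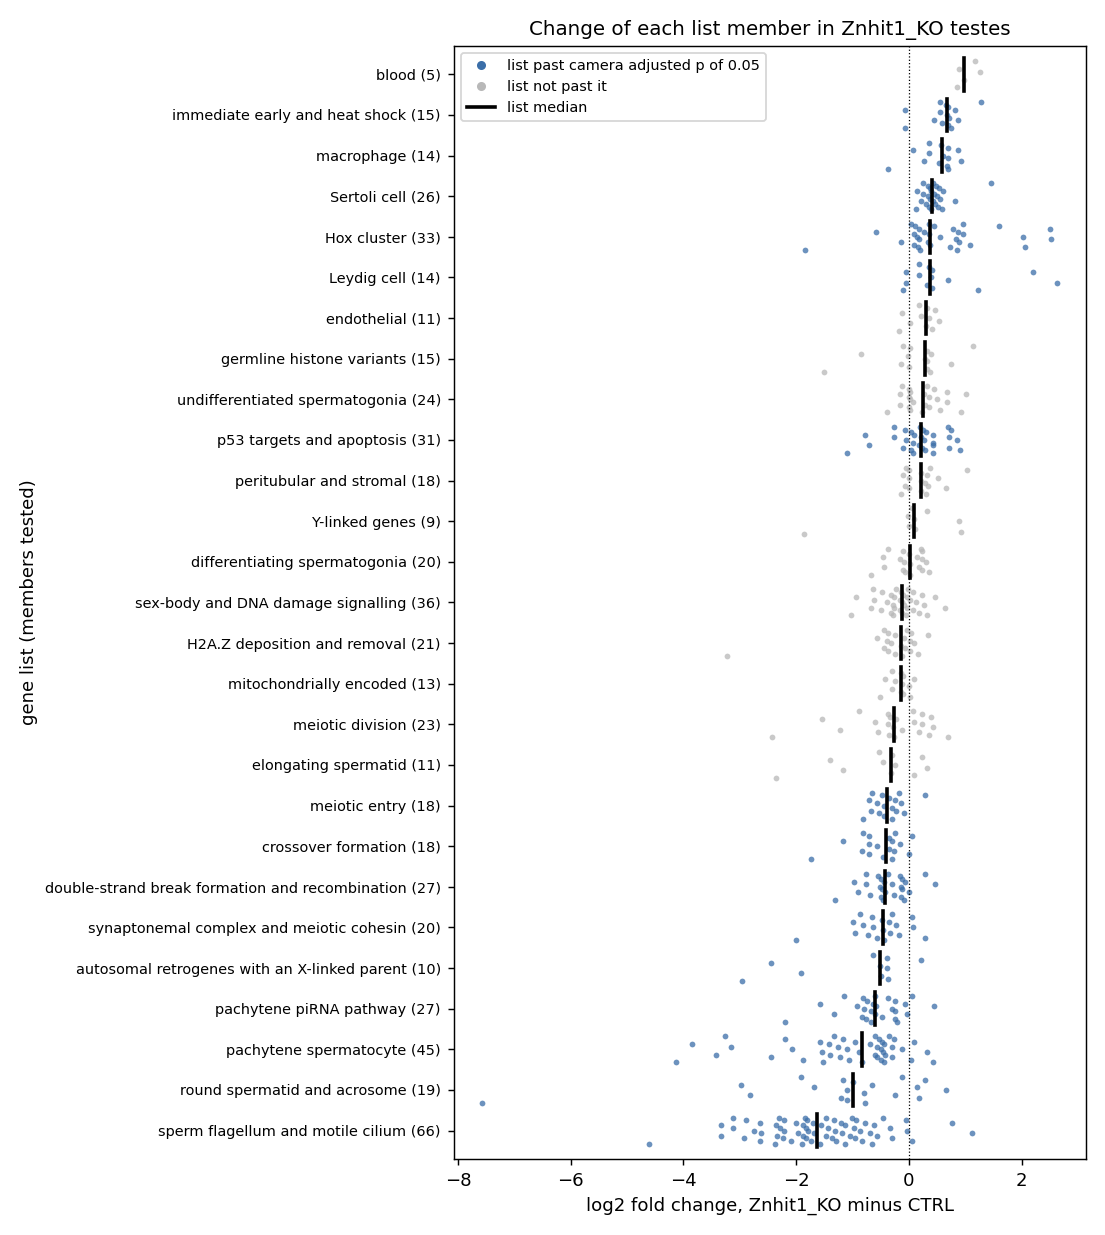
Each point is the log2 fold change (x axis, Znhit1_KO minus CTRL) of a tested member of 1 of the 27 gene lists (y axis, with the number of members tested), and black bars are list medians. The flagellum list has the lowest median, -1.63; blue marks the 15 lists past a camera adjusted p of 0.05, none of which passed with an estimated correlation.

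Pachytene spermatocyte genes and the piRNA pathway were also lower as groups. Piwil1, the PIWI protein of pachytene piRNAs, stood at 560.2 ± 302.4 CPM in CTRL and 188.6 ± 80.6 in Znhit1_KO (SD, n = 2). Ldhc, the germ cell lactate dehydrogenase, stood at 329.6 ± 216.5 and 89.4 ± 47.9 CPM. The log2 changes of Spink2 (-3.15, SE 0.594), Nme5 (-2.08, SE 0.346), Spata16 (-3.27, SE 0.707) and Crisp2 (-3.43, SE 0.752) were larger. Hspa2, the most abundant pachytene marker, changed by -0.89 (SE 0.310) and Cdk1 by 0.43 (SE 0.235). Of the 45 pachytene genes, 41 had a negative change and 25 were lower in both Znhit1_KO libraries than in both CTRL libraries. Adjusted over the list alone, edgeR called 5 lower (Nme5, Adam3, Spink2, Spata16 and Crisp2), against 0 over all genes. Over the list alone edgeR called 8 with total count scaling and 17 with Sertoli list scaling, while DESeq2 called 20 and limma-voom 4. The authors' deposited table marks 13 lower. The median was -0.82 with a camera adjusted p of 1.15e-08, and p = 0.334 with an estimated correlation. The list's mean relative to all 4 libraries was 0.0748 and 1.01 in CTRL replicates 1 and 2 and -0.845 and -0.244 in Znhit1_KO replicates 1 and 2. Without CTRL replicate 2 the pachytene median was -0.27. Without Znhit1_KO replicate 1 it was -0.55 and 0 members passed over the list alone, and without CTRL replicate 1 it was -1.24 and 35 passed. Without Znhit1_KO replicate 2, 14 passed.

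The piRNA list of 27 genes had a median of -0.61, a camera adjusted p of 1.54e-05 and p = 0.32 with an estimated correlation. Tdrd6 (-2.20, SE 0.548) and Ddx25 (-1.33, SE 0.340), both components of the germ cell RNA granule, are marked lower with Piwil1 in the authors' deposited table. Of the 27, 18 were lower in both Znhit1_KO libraries than in both CTRL libraries, and edgeR called 0 adjusted over the list alone and 0 over all genes, with 13 at an unadjusted p under 0.05. Adjusted over the list alone, edgeR called 16 without CTRL replicate 1, 11 with total count scaling and 14 with Sertoli list scaling, and DESeq2 called 13. The piRNA median was -0.38 without CTRL replicate 2 and -0.85 without CTRL replicate 1. Piwil2 (-0.80, SE 0.269) and the helicase gene Ddx4 (-0.75, SE 0.250) had smaller changes, and Tex19.1 had a positive one (0.44, SE 0.174). Genes of the round spermatid and acrosome had a median of -0.99 over 19 tested members, with a camera adjusted p of 9.67e-05 and p = 0.183 with an estimated correlation. Of these genes edgeR called 0 adjusted over the list alone and 0 over all genes, with 7 at an unadjusted p under 0.05. Adjusted over the list alone, 10 were called without CTRL replicate 1 and 6 with total count or Sertoli list scaling, and 8 by DESeq2. The median of this list was -0.53 without CTRL replicate 2 and -1.34 without CTRL replicate 1. Acrbp (-1.68, SE 0.50) and Zpbp2 (-1.91, SE 0.405) are marked lower in the authors' deposited table. Of 10 autosomal retrogenes with an X-linked parent, which stand in for silenced X-linked genes during meiosis, Cetn1 (-2.97, SE 0.547) passed adjusted over the list alone and 0 passed over all genes. Their median was -0.51 with a camera adjusted p of 0.013 and p = 0.396 with an estimated correlation. The retrogene call was lost without CTRL replicate 2 (median -0.027, adjusted p 0.213) and without Znhit1_KO replicate 1 (median -0.24, adjusted p 0.243). The median was -0.85 without CTRL replicate 1 and -0.89 without Znhit1_KO replicate 2. Adjusted over the list alone, 8 retrogenes passed without CTRL replicate 1 and 3 with total count or Sertoli list scaling.

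**Figure D2:**
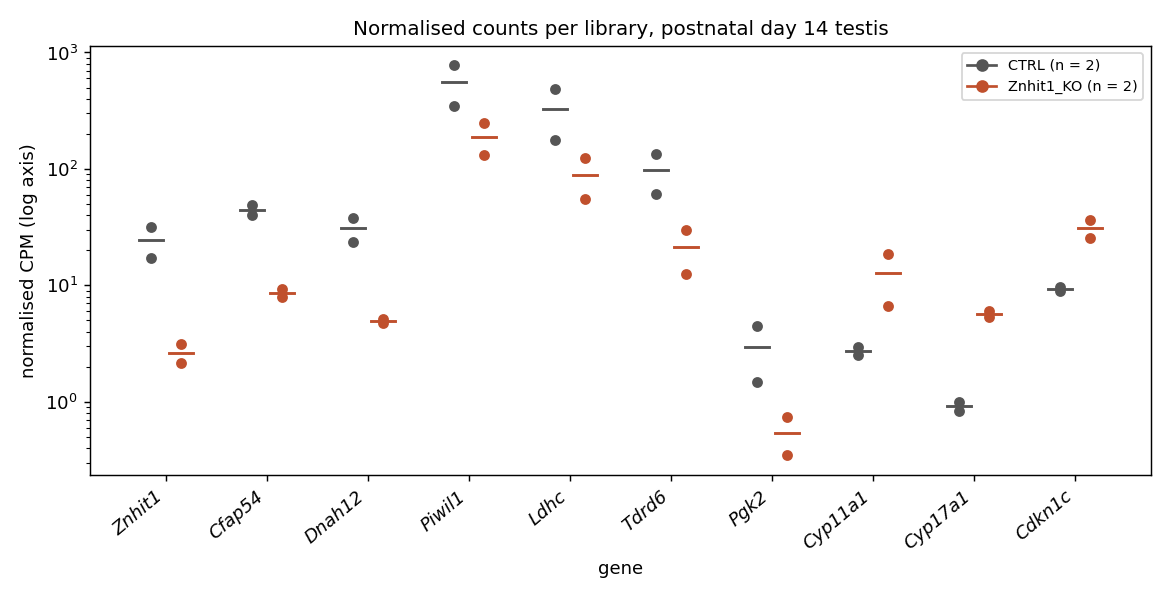
Normalised CPM (log axis) of 10 genes (x axis) in each library; points are libraries and bars are group means (n = 2 per group). Znhit1 stands at a mean of 24.6 CPM in CTRL and 2.64 CPM in Znhit1_KO, and the CTRL libraries lie farther apart for Piwil1, Ldhc and Tdrd6 than for Cfap54.

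Lists of genes of meiotic entry, double-strand breaks, the synaptonemal complex and crossover formation were lower, with smaller medians. The crossover genes Ccnb1ip1, a SUMO or ubiquitin ligase family member (-1.74, SE 0.246), and Rnf212 (-1.18, SE 0.243), the telomere attachment gene Terb2 (-2.00, SE 0.369) and the meiotic recombination gene Spata22 (-1.31, SE 0.212) had the strongest changes among those named here, all with no overlap between groups. Stag3 (-0.35, SE 0.203), Sycp1 (-0.46, SE 0.318) and Brca2 (-0.26, SE 0.188) had smaller ones. For crossover formation the median over 18 genes was -0.41 with a camera adjusted p of 2.03e-05, and p = 0.0853 with an estimated correlation; Ccnb1ip1, Rnf212, Mlh3, Msh4 and Shoc1 passed adjusted over the list alone. The 20 synaptonemal complex and cohesin genes had a median of -0.47 (camera adjusted p of 7.13e-05; p = 0.356 with an estimated correlation), with 6 passing adjusted over the list alone. The 27 genes of double-strand break formation and recombination had a median of -0.43 (camera adjusted p of 0.000257; p = 0.137 with an estimated correlation), with Ankrd31 and Spata22 passing adjusted over the list alone. The 18 meiotic entry genes had a median of -0.39 (camera adjusted p of 0.000602; p = 0.157 with an estimated correlation), and Smc1b, Stra8, Gm4969 and Ythdc2 passed adjusted over the list alone. In each of these 4 lists 0 genes passed edgeR over all genes. Without CTRL replicate 2 the medians of the synaptonemal complex and entry lists were -0.16 and -0.21, and without Znhit1_KO replicate 1 both were -0.23. Without CTRL replicate 1 they were -0.77 and -0.47, and without Znhit1_KO replicate 2 they were -0.83 and -0.58. The counts adjusted over the list alone were not stable with 1 library left out, and mostly fell. Such a fit leaves 1 library in a group and fewer degrees of freedom, so a lower count does not show that the calls rest on a single library. The medians of all 4 lists stayed negative whichever library was left out.

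Markers of Sertoli cells, Leydig cells and macrophages had positive medians, though the macrophage list mean overlapped between groups. All 26 Sertoli cell markers had a positive log2 change and 15 were higher in both Znhit1_KO libraries than in both CTRL libraries. Clu stood at 3759 ± 250.7 CPM in CTRL and 4656 ± 468.7 in Znhit1_KO (SD, n = 2) and Aard at 735.8 ± 68.6 and 1022 ± 28.2. The Sertoli median was 0.41, with a camera adjusted p of 1.54e-05 and p = 0.264 with an estimated correlation. Without Znhit1_KO replicate 1 it was 0.18 (adjusted p of 0.0182). Of these markers edgeR called 0 adjusted over the list alone and 0 over all genes, with 7 at an unadjusted p under 0.05. The authors' deposited table marks Ptgds (1.45, SE 0.387 in the edgeR fit) higher. Among 14 Leydig cell genes, Cyp17a1, an enzyme of androgen synthesis, stood at 0.917 ± 0.118 CPM in CTRL and 5.65 ± 0.452 in Znhit1_KO (SD, n = 2). It was the 1 member called adjusted over the list alone, with 0 called over all genes, whereas Nr5a1 (0.40, SE 0.170) and Scarb1 (0.31, SE 0.149) did not. The Leydig median was 0.37 (camera adjusted p of 0.00757; p = 0.145 with an estimated correlation), and its call was lost without CTRL replicate 1 (median 0.14, adjusted p 0.256) and without Znhit1_KO replicate 2 (median 0.10, adjusted p 0.223). Without CTRL replicate 2 the Leydig median was 0.74 and the macrophage median 0.96. The 14 macrophage markers had a median of 0.58 (camera adjusted p of 0.013; p = 0.459 with an estimated correlation), a call lost without CTRL replicate 1 and without Znhit1_KO replicate 2 (medians 0.24 and 0.053, adjusted p 0.51 and 0.467). EdgeR called 0 macrophage markers adjusted over the list alone and 0 over all genes, with 1 at an unadjusted p under 0.05. The authors' deposited table marks 0. Relative to all 4 libraries, the macrophage mean was -0.549 and 0.0646 in CTRL replicates 1 and 2. In Znhit1_KO replicates 1 and 2 it was -0.0876 and 0.572. The Leydig mean was -0.513 and -0.0936 in CTRL, and -0.0288 and 0.636 in Znhit1_KO, in the same order. Both Znhit1_KO libraries exceeded both CTRL libraries for 5 of 14 macrophage and 6 of 14 Leydig genes.

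Immediate early and heat shock genes, which respond to handling of tissue, had a median of 0.67 over 15 genes (camera adjusted p of 6.04e-05; p = 0.108 with an estimated correlation). Egr1 stood at 107.8 ± 10.9 CPM in CTRL and 179.7 ± 49.0 in Znhit1_KO (SD, n = 2), and Dnajb1 changed by -0.077 (SE 0.170). The 33 Hox genes had a median of 0.38 (camera adjusted p of 9.67e-05; p = 0.0427 with an estimated correlation, adjusted p = 0.465). The authors' deposited table marks Hoxd13 (2.5, SE 0.533) and Hoxd9 higher and Hoxa4 (-1.84, SE 0.732) lower. Without CTRL replicate 1 the Hox median was 0.74. The 31 p53 target and apoptosis genes had a median of 0.22 (camera adjusted p of 0.0467; p = 0.19 with an estimated correlation), a call lost without any 1 of the libraries, with adjusted p between 0.0932 and 0.15, and with no filter on low counts (adjusted p of 0.0722). Without Znhit1_KO replicate 1 the p53 median was 0.065. In each of these 3 lists edgeR called 0 genes adjusted over the list alone and 0 over all genes, with 9 immediate early, 3 Hox and 3 p53 genes at an unadjusted p under 0.05. For the immediate early list, edgeR called 7 adjusted over the list alone with total count scaling, 6 without Znhit1_KO replicate 1, 6 on counts divided by 4 and 3 without CTRL replicate 1, and DESeq2 called 9. Without Znhit1_KO replicate 2 its median was 0.42. Scaling on the Sertoli list moved the median of all genes from 0.0315 to -0.40. Under it the medians of the Sertoli (-0.035), Leydig (-0.069), Hox (-0.043) and p53 (-0.23) lists were negative, though above the median of all genes, while those of the immediate early (0.25) and macrophage (0.17) lists stayed positive.

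**Figure D3:**
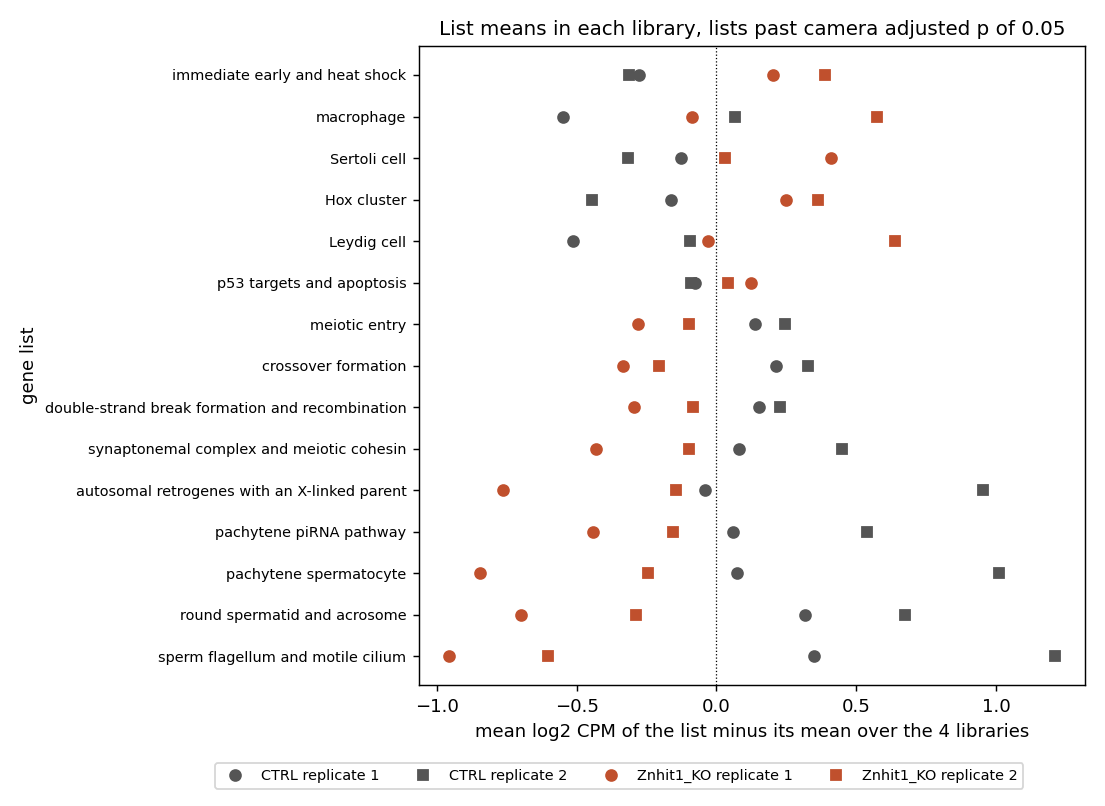
Mean log2 CPM of each list past a camera adjusted p of 0.05, relative to its mean over the 4 libraries (x axis), with a symbol per library and lists on the y axis. For the flagellum list CTRL replicate 2 lies at 1.21 and CTRL replicate 1 at 0.35, while the Znhit1_KO libraries lie at -0.95 and -0.60.

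The other lists did not pass camera. Undifferentiated spermatogonia markers had a median of 0.25 (adjusted p of 0.0618; p = 0.439 with an estimated correlation), with Uchl1 at -0.0021 (SE 0.140). The median of differentiating spermatogonia markers was 0.011 while their mean was -0.028 (adjusted p of 0.825; p = 0.832 with an estimated correlation). Peritubular and stromal (0.21, adjusted p of 0.095; p = 0.186 with an estimated correlation), endothelial (0.29, adjusted p of 0.117; p = 0.466) and blood markers (0.98, adjusted p of 0.41; p = 0.734) had positive medians, as did germline histone variants (0.29, adjusted p of 0.122; p = 0.455) and 9 Y-linked genes (0.086, adjusted p of 0.294; p = 0.59). Mitochondrially encoded genes (-0.14), sex-body and DNA damage signalling genes (-0.13) and elongating spermatid genes (-0.31) each had an adjusted p of 0.095, with p = 0.531, 0.171 and 0.254 with an estimated correlation. Meiotic division genes had a median of -0.26 (adjusted p of 0.112; p = 0.612 with an estimated correlation), with Meikin, a kinetochore regulator of meiosis I, at -2.42 (SE 0.368). Of the lists in this paragraph, all but the Y-linked, stromal and differentiating spermatogonia ones passed camera in at least 1 other setting. Leaving out 1 library moved several medians: elongating spermatid genes to -0.95 without Znhit1_KO replicate 2 (adjusted p of 0.0108) and -0.52 without CTRL replicate 2 (adjusted p of 0.0403), endothelial markers to 0.050 without Znhit1_KO replicate 2, and meiotic division genes to -0.081 without CTRL replicate 2. Adjusted over the list alone, edgeR called 2 elongating spermatid genes and 1 meiotic division gene, 0 in the others of this paragraph, and 0 over all genes in any of them. At an unadjusted p under 0.05 there were 2 undifferentiated and 2 differentiating spermatogonia markers, 3 Y-linked, 2 mitochondrial, 5 sex-body, 3 elongating spermatid and 4 meiotic division genes, and 0 stromal, endothelial, blood or histone genes. Of the 27 lists, 15 passed camera, 9 lower and 6 higher, 0 passed with an estimated correlation, where 1 had an unadjusted p under 0.05, and 0 passed with fry, whose lowest adjusted p was 0.152. With few degrees of freedom, the test with an estimated correlation could hardly pass a list after adjustment over 27 lists. For the Hox list the estimated correlation, 0.00166, was below the preset 0.01. Its unadjusted camera p still rose from 2.89e-05 to 0.0427.

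X-linked genes were seldom among the decreases. In meiosis the X chromosome is silenced from the pachytene stage, so that it holds few genes of late spermatocytes. The authors' deposited table marks 3 of 952 X-linked genes lower (0.315%; Hsf3, Gm10439 and Gm773), against 803 of 24176 autosomal genes (3.32%), an odds ratio of 0.092 (95% interval 0.0189 to 0.271, Fisher's exact p = 2.19e-10). It marks 2 X-linked genes higher (Irs4 and 1700080O16Rik) and 68 autosomal ones (Fisher's exact p = 1). Of 917 X-linked genes tested, the median log2 change was 0.21, against 0.023 for autosomal genes, and both Znhit1_KO libraries exceeded both CTRL libraries for 33.6% of X-linked and 21.4% of autosomal genes, where chance gives 16.7%. Camera gave p = 0.000294 for the X-linked genes, and p = 0.186 with an estimated correlation. Fisher's exact test treats genes as independent, so its p-values and interval do not measure variation between animals. Because genes vary together, a share above 16.7% can also arise without a difference between the groups. On the Y chromosome the authors' deposited table marks Rbmy, Gm10352, Gm21704, Gm10256 and Gm3376 lower; Rbmy and clone-named Y genes belong to multicopy families whose reads cannot be assigned to a copy with certainty.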

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

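DESeq2 combined with other choices, and counts divided by 4, were tried only after the data were seen. The count of changed genes depended on the test. It was 0 with edgeR under DESeq2 size factors, total count scaling, Sertoli list scaling, no filter, a filter of at least 50 counts in 2 libraries and counts divided by 4, and 0 with limma-voom, but 1027 with DESeq2 (924 with a fold of at least 2). Leaving out 1 library gave 0 to 754 genes, and 0 to 754 with a fold of at least 2, the 754 without CTRL replicate 1; a test against a fold of 2 gave 0. DESeq2 gave 1357 genes without CTRL replicate 1 (1313 with a fold of at least 2), 283 without CTRL replicate 2 (283), 474 without Znhit1_KO replicate 1 (474) and 824 without Znhit1_KO replicate 2 (824). It gave 1428 with Sertoli list scaling (1427), 1052 with total count scaling (916) and 771 on counts divided by 4 (708). With Sertoli list scaling 29 of the 1428 were higher, against 102 of 1027. With the replicate number as a block, edgeR called 2737 genes, 814 higher and 1923 lower (1196 with a fold of at least 2), and DESeq2 called 3812 (1154 with a fold of at least 2). The labels do not say that a number marks a shared litter or day; deviations of same-numbered libraries correlated at 0.421 across genes, and 2 pairs are too few to show pairing. Parting the libraries by number gave 402 DESeq2 genes and the crossed parting 13, against 1027 for the real groups. At an unadjusted p under 0.05 edgeR gave 2386 by number and 84 crossed, against 2590; 3 partings are too few for a share under 0.05. The cause of these differences between tests was not tested.

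Znhit1 kept its direction in every setting tried and passed the threshold with DESeq2 (log2 change -3.23), with the replicate block (-3.17) and without CTRL replicate 1; leaving out 1 library gave -3.60 to -2.71. From 14 to 17 lists passed camera with 1 library left out and 15 to 19 with other scalings, filters or the block; 0 passed with an estimated inter-gene correlation and 0 with fry. The X-linked median exceeded the autosomal one by 0.19, and by 0.12 to 0.25 with 1 library left out. The camera call was lost with an estimated inter-gene correlation, where the difference was the same 0.19. That test also has far fewer degrees of freedom, so the loss is not shown to come from genes varying together. No named gene that changed sign passed the threshold after it. With Sertoli list scaling, which lowers all log2 changes, the genes that changed sign were Mki67 (-0.28), Cdh5 (-0.12), H3f3a (-0.42), Trrap (-0.12), Ep400 (-0.42), Hoxb9 (-0.064), Scarb1 (-0.12), Nr5a1 (-0.038), Mrc1 (-0.35), mt-Cytb (-0.44), Sesn2 (-0.19), Col1a2 (-0.20), Clu (-0.14), Trim28 (-0.41) and Eif2s3y (-0.36). With total count scaling they were mt-Co1 (0.011), Uchl1 (0.017) and Uba1y (0.0079), with DESeq2 size factors H3f3a (-0.0027), with the replicate block mt-Cytb (-0.00040) and with counts divided by 4 Uchl1 (0.0052). With 1 library left out, ranges were -0.76 to 0.12 for Rpl10l, -1.73 to 3.09 for Hbb-bs, -1.48 to 3.07 for Hba-a1, -0.30 to 0.00077 for Top2a, -0.15 to 0.51 for Mki67, -0.49 to 0.042 for Odf2, -0.35 to 0.16 for H3f3b. They were -0.24 to 0.30 for H3f3a, -0.053 to 0.66 for Trrap, -0.077 to 0.045 for Ep400, -0.22 to 0.083 for Dnajb1, -0.0085 to 0.13 for Mrc1, -0.057 to 1.34 for Csf1r, -0.34 to 0.20 for mt-Co1. Further ranges were -0.30 to 0.23 for mt-Cytb, -0.11 to 0.53 for Sesn2, -0.51 to 0.012 for Mdm2, -0.22 to 0.12 for Acta2, -0.20 to 0.28 for Trim28. Others were -0.067 to 0.064 for Uchl1, -0.082 to 0.025 for Uba1y and -0.082 to 0.12 for Eif2s3y. For list medians they were -1.73 to 3.08 for blood and -0.072 to 0.13 for differentiating spermatogonia. Medians also changed sign for undifferentiated spermatogonia (-0.0038 without Znhit1_KO replicate 1), germline histone variants (-0.022 without CTRL replicate 1), and Y-linked (-0.016) and mitochondrially encoded genes (0.016) without Znhit1_KO replicate 2. With DESeq2 size factors the differentiating spermatogonia median was -0.0022. With Sertoli list scaling the medians of the Sertoli (-0.035), Leydig (-0.069) and Hox (-0.043) lists were negative while camera, which compares a list with all other genes, still called them higher. Those of the p53 (-0.23), Y-linked (-0.34), endothelial (-0.12), histone (-0.15), stromal (-0.22), undifferentiated (-0.21) and differentiating spermatogonia (-0.43) lists turned negative without a call. With the replicate block the H2A.Z list passed (adjusted p of 0.0415), and more members passed when adjusted over the list alone. The block gave 59 flagellum genes, 39 pachytene, 21 piRNA, 12 round spermatid, 9 retrogenes, 12 crossover, 15 synaptonemal complex, 16 double-strand break and 14 entry genes. It gave 22 Sertoli, 5 Leydig, 4 macrophage, 13 immediate early, 3 Hox and 7 p53 genes, and 8 H2A.Z genes, 7 of them lower. The cause of these was not tested, apart from the lowering that Sertoli list scaling makes by construction.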

Other observations

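The tests of symbol families, of the control difference, of other cell types and of a somatic share were chosen after the results were seen; the comparisons with matched random lists were fixed before theirs were. Beyond the lists, genes whose symbols share a stem were counted among the lower calls of the authors' deposited table, which hold 609 of 16974 protein-coding genes tested. Of 310 stems with at least 8 genes, 10 were enriched by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. Cilia and flagella associated genes (Cfap) had 18 of 32 members called lower (adjusted p = 6.94e-16), axonemal dynein heavy chains (Dnah) 9 of 15 (adjusted p = 3.96e-08), coiled-coil genes (Ccdc) 28 of 134 (adjusted p = 4.64e-12) and tetratricopeptide genes (Ttc) 10 of 40 (adjusted p = 8.15e-05). The Lrrc (10 of 55), Mroh (4 of 8), Tcp (4 of 8), Abca (5 of 16), Prss (5 of 24) and Spata (5 of 24) stems followed, with adjusted p between 0.00139 and 0.0437. The Tcp stem includes near-identical Tcp10 copies, and stems share genes with the flagellum list, so these counts are not independent of it. Fisher's exact test also treats genes as independent, so its p-values do not measure variation between animals.

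Some single genes outside the naming rule, chosen after their values were seen, went from near absence to clear expression. Cldn23, a claudin gene (chromosome 8, 35824712 to 35826559, mm10), stood at 0.0861 ± 0.0667 CPM in CTRL and 7.0 ± 1.17 in Znhit1_KO (SD, n = 2), and Slc7a11, the cystine transporter gene, at 0.395 ± 0.0248 and 3.63 ± 0.822. In the other direction Pudp went from 3.45 ± 2.08 to 0.0560 ± 0.0283 CPM, Abca14 from 4.32 ± 1.82 to 0.152 ± 0.00909 and Spata31d1a from 8.39 ± 3.36 to 0.505 ± 0.0603. The authors' deposited table also marks Mir8114 higher, which overlaps the start of Glul, so that its reads cannot be told from those of Glul (260.4 ± 43.8 and 336.4 ± 5.07 CPM). None of these passed edgeR over all genes, where 2590 had an unadjusted p under 0.05 and DESeq2 called 1027. Of the 15 other genes tested within 1000000 bp of Cldn23, the authors' deposited table marks 0. Their log2 changes ran from -7.06 to 0.926, with a median of 0.165, against 6.32 for Cldn23. The cause of the lowest of them was not tested.

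The lower flagellum and pachytene transcripts are a pattern in which stage and genotype are hard to separate, because the libraries within each group differ along the same genes. Length and GC content are argued against: the flagellum median of -1.63 lay below all of 10000 random lists matched on length, GC content and expression, at percentile 0, where the lowest random median was -0.25. A less advanced wave of spermatogenesis, or fewer late spermatocytes, stays open. Across 24116 genes the change in Znhit1_KO correlated with the difference between CTRL replicate 2 and CTRL replicate 1 at r = -0.29. Both are computed from the same CTRL libraries, so unequal noise in them could give a negative r without any difference in stage, and this test decides nothing. Within groups, the flagellum list's median difference, replicate 2 minus replicate 1, was 1.04 in CTRL and 0.472 in Znhit1_KO. Of 807 tested lower calls of the authors' deposited table, 759 were higher in CTRL replicate 2 than in CTRL replicate 1. In Znhit1_KO 640 of them were higher in replicate 2. These values do not tell stage from genotype. A lower share of later germ cells that raises all other cell types alike also stays open: 6 lists of other cell types all had positive medians, from 0.21 to 0.58, and differed among themselves in a permutation test of their members' fitted changes (p = 0.0231), but on log2 CPM the permutation p was 0.0333 for the groups, 0.0001 for libraries parted by replicate number and 0.0571 for the crossed parting, so the test cannot separate the explanations. Loss of ZNHIT1 itself, named by the design, also stays open, as no test here tells it from these.

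The 222 tested members of developmental transcription factor families, chosen after some were noticed among the calls, had a median log2 change of 0.36, with a camera p = 1.43e-07 and p = 0.132 with an estimated correlation, and 96 were higher and 21 lower in both Znhit1_KO libraries than in both CTRL libraries. The authors' deposited table marks 9 of the members higher and 3 lower, the calls that prompted the choice of these families, and Foxa2 stood at 0.355 ± 0.104 CPM in CTRL and 3.82 ± 0.530 in Znhit1_KO (SD, n = 2). The median of all 222 members, 0.36, lay above all 10000 lists matched on expression (percentile 100). So did the median of 0.35 of the 210 members that the authors' deposited table does not mark. Low expression by itself is therefore argued against. Chance is not excluded, since the random lists ignore that members vary together and the families were chosen after calls were seen. A higher share of somatic cells stays open for the class as a whole. The class median exceeded that of 83 somatic markers by 0.00201 (95% bootstrap interval -0.0698 to 0.116). Markers of undifferentiated spermatogonia, which are not somatic cells, also had a positive median, 0.25. Similar medians therefore do not single out a somatic share. The bootstrap resampled genes and holds no variation between libraries, so the interval may be too narrow. For the 9 called members a higher somatic share cannot be told apart from an effect of ZNHIT1 loss. Their median of 1.75 exceeds the 95th percentile of the somatic markers, 1.015, but they were picked because they had risen.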
